A study of Homo sapiens with 6 samples.

How the data were processed

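RNA was measured by sequencing in 6 libraries of Huh7 cells, an established human hepatocellular carcinoma line. Per the labels, 3 libraries came from control cultures and 3 from cultures given GABA (gamma-aminobutyric acid) for 24 h, and each group's libraries are named as biological replicates 1, 2 and 3. The dose of GABA is not stated in the labels. The deposited values are integer read counts per gene, with Ensembl gene identifiers and 1 file per library. Per the submitters' processing notes, CASAVA 1.8 and Bowtie 0.12.2 were used with the hg38 build. The notes do not give the counting program, the annotation release or whether counting used the strand, so counts of overlapping genes are uncertain.

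The files list 5187 genes in the same order in all 6 libraries, which is a part of the annotated genes. All 5187 identifiers were found in GENCODE release 29 on the same build, with 4449 protein-coding genes, 482 long noncoding genes, 211 pseudogenes and 45 of other types. Symbols came from a gene name table for 4904 genes and from GENCODE release 29 for 283. The list follows the comparison itself. Across the tested genes, the position of a gene in the files and its p-value for GABA against control had a Spearman correlation of 0.93, and no tested gene had an absolute log2 fold change below 0.12. The labels state no such selection. Genes that did not change are therefore nearly absent from the files, and the number of changed genes, the adjusted p-values and the tests of gene lists are descriptions of a preselected set. Each list was compared only with the other listed genes, and the totals per library (7702666 to 8392945 counts) are sums over the listed genes, not library depths. CPM values are TMM-scaled counts relative to the total on the listed genes.

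Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr (minimum count 10, minimum total count 15), TMM normalization, a robust quasi-likelihood fit and the quasi-likelihood F test for GABA against control, with the Benjamini-Hochberg adjustment and a threshold of 0.05. The filter left 4981 genes and removed 206. Fold changes are GABA over control on the log2 scale, with the standard error from the fit; levels are means with SD over 3 libraries. Before the data were examined, 51 gene lists, the test, the alternatives and the rule for naming genes were fixed. The 40 lists with at least 5 tested genes were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and the p with an estimated correlation was computed beside it. The other 11 lists were not tested with camera. The direction of the changed genes in each list was also compared with that of the other listed genes by Fisher's exact test, adjusted over the 51 lists.

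Genes were named by 3 parts of that rule. The first took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups. The second took up to 4 genes with the smallest p from each list whose test passed and from 7 lists chosen for the question: GABA metabolism, GABA receptors, mesenchymal state, epithelial state, matrix proteases, hepatocyte secreted proteins and the mitotic cell cycle. The third always took GAD1, ABAT, CDH1, VIM, AFP, ALB and MKI67. The same ranking among genes with a mean of at least 50 CPM was added after the values had been seen, because the first part took only genes with low counts. Some genes that the rule takes are not named in the text. Other genes named in the text were also chosen after their values were seen.

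The scripts were tested on simulated data. Counts for this comparison were drawn from the real means and library totals, with known changes in part of 4951 tested genes. The test found 81.0% of genes with a simulated log2 change of 0.5 and 94.9% of those with a change of 1, and called 0.40% of the 4732 unchanged genes. A simulated change of the DNA replication list was found, and 0 of the other 39 lists were called. Genes were drawn independently and most were unchanged. The simulation therefore does not test list calls among correlated genes or in a preselected set.

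The alternatives were DESeq2 size factors in edgeR, upper quartile scaling, library size only, no filter, a mean count of 10 or more, DESeq2 1.42.0, limma-voom, a minimum absolute log2 fold change of 1, the replicate number as a block, each library left out in turn, camera with an estimated correlation and fry. A scaling set to the gene order of the files, a scaling without mitochondrially encoded genes, and a correction for transcript length and GC content were added after the data had been seen. Settings that apply only to normalized values were not run on counts. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled tables and figures. No library was left out of the reported values.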

Results

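The comparison asked which transcripts changed when GABA was added to liver cancer cells, in a series about GABA as a regulator of genes in metastasis of this cancer. RNA was sequenced from 3 control and 3 GABA-treated Huh7 cultures after 24 h. Counts on the listed genes summed to 8235028, 7702666 and 8027757 in control replicates 1, 2 and 3, and to 7719243, 7746996 and 8392945 in GABA replicates 1, 2 and 3. The first principal component held 79.9% of the variance and separated the groups, as the choice of listed genes by this comparison would bring about. The second held 9.31% and set control replicate 3 apart from the other control libraries. Mitochondrially encoded transcripts made up 9.11% of the counts in that library, against 7.74% and 7.15% in control replicates 1 and 2 and 6.66% to 7.04% in the GABA libraries.

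**Figure D1:**
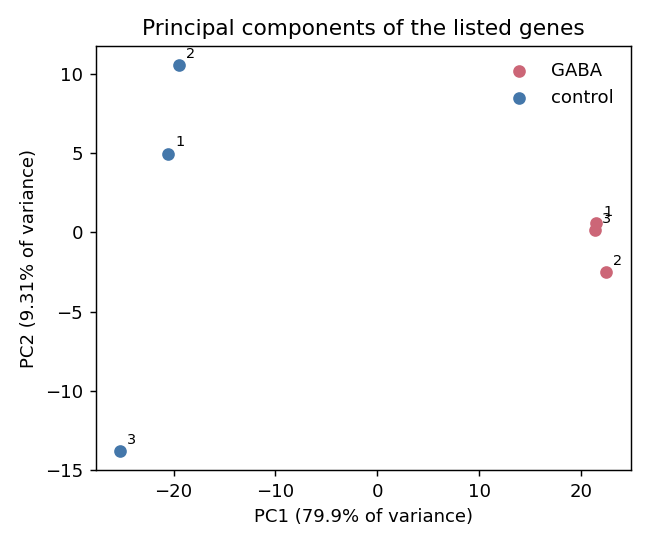
Principal components of log2 CPM over the listed genes, with 1 point per library, coloured by group and numbered by replicate. PC1 (79.9% of the variance) separates control from GABA on genes listed because they differ between them, and control replicate 3 lies apart on PC2 (9.31%).

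GABA-treated cells had more transcripts of the mitosis, DNA replication and cholesterol lists and fewer of the ATF4 and NRF2 lists. These 5 lists passed camera with a preset correlation, and none passed with an estimated correlation (adjusted p = 0.70 for each). MKI67, a proliferation marker, rose from 377 ± 16.2 to 643 ± 46.0 CPM (counts scaled to the listed genes; SD, n = 3), and DHCR7, the last enzyme of cholesterol synthesis, rose from 79.2 ± 8.59 to 159 ± 2.57. DDIT3, the stress factor CHOP, fell from 472 ± 21.8 to 266 ± 5.78, and SQSTM1, the autophagy receptor p62 and an NRF2 target, fell from 4220 ± 231 to 2473 ± 38.6. PLAT, FN1 and IL1B were higher, and SPARC and CCL5 were lower. Of the 4981 genes tested with edgeR, 2369 were higher and 2549 lower with GABA. Most changes were small, with a median absolute log2 fold change of 0.40 (quartiles 0.28 and 0.63) and 515 genes at 1 or more. In 4608 genes (92.5%) the groups did not overlap, where chance gives 10%, but the files list few genes without a change, so these counts do not measure how much of the transcriptome responded.

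All 28 tested genes of the mitotic cell cycle list rose, with a median log2 fold change of 0.54 (camera adjusted p = 5.8e-06; adjusted p = 0.70 with an estimated correlation). The smallest p-values were those of UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, at 0.78 ± 0.07 (SE, adjusted p = 5.4e-06), and MKI67 at 0.77 ± 0.07 (adjusted p = 7.2e-06). CENPF, a kinetochore protein, rose by 0.78 ± 0.08, and CDC20, the activator of the same complex as UBE2C, by 0.77 ± 0.08. The 22 tested genes of the DNA replication list also rose, with a median of 0.49 (camera adjusted p = 1.5e-04; adjusted p = 0.70 with an estimated correlation). Among them were the replicative helicase genes MCM7 (0.50 ± 0.07) and MCM2 (0.58 ± 0.09), their partner CDC45 (0.60 ± 0.10), and TYMS (0.76 ± 0.12), the thymidylate synthase, of whose exons 46.6% overlap another gene. The replication-dependent histone list did not pass, with 2 of its 6 tested genes up and 4 down (camera adjusted p = 0.72).

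Cholesterol synthesis and uptake was the other list with higher values, with 10 of 11 tested genes up and 1 down (median 0.48; camera adjusted p = 0.017; adjusted p = 0.70 with an estimated correlation). DHCR7 rose by 1.01 ± 0.09 (adjusted p = 5.4e-06). ACAT2, an acetyl-CoA acetyltransferase, rose by 0.62 ± 0.09, although 52.3% of its exon length overlaps another gene. SREBF2, the transcription factor of the pathway, rose by 0.48, and GGPS1, which makes geranylgeranyl diphosphate, was the gene that fell, by 0.61.

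The ATF4 and amino acid response list was lower, with 16 of 19 tested genes down, 1 up and 2 not passing (median -0.35; camera adjusted p = 0.012; adjusted p = 0.70 with an estimated correlation). DDIT3 had a log2 fold change of -0.83 ± 0.06 (adjusted p = 2.5e-06). DDIT4, an inhibitor of mTORC1 also known as REDD1, had -1.20 ± 0.12 (adjusted p = 1.7e-05). Their exon overlaps with other genes were 39.6% and 41.2%. VLDLR, a lipoprotein receptor, had -0.73 ± 0.11. ATF4 itself had -0.15, and AARS1, the alanyl-tRNA synthetase, went the other way at 0.52 ± 0.08. The amino acid transporters SLC7A5 (-0.38) and SLC7A11 (-0.26) also fell.

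In the NRF2 and oxidative stress list, 17 of 19 tested genes fell and 2 rose (median -0.40; camera adjusted p = 0.012; adjusted p = 0.70 with an estimated correlation). SQSTM1 had -0.77 ± 0.06 (adjusted p = 3.0e-06), and OSGIN1, an oxidative stress-induced growth inhibitor, had -1.10 ± 0.11 (adjusted p = 1.9e-05). GSR, the glutathione reductase, and NQO1, the quinone reductase, each had -0.71, with SE of 0.07 and 0.10. NFE2L2, which encodes NRF2, had -0.34. The exceptions were HMOX1, the heme oxygenase, at 0.50 and PGD, of the pentose phosphate pathway, at 0.47. Adjusted over the list alone, 28, 22, 11, 17 and 19 genes passed in these 5 lists, the same counts as over all genes.

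**Figure D2:**
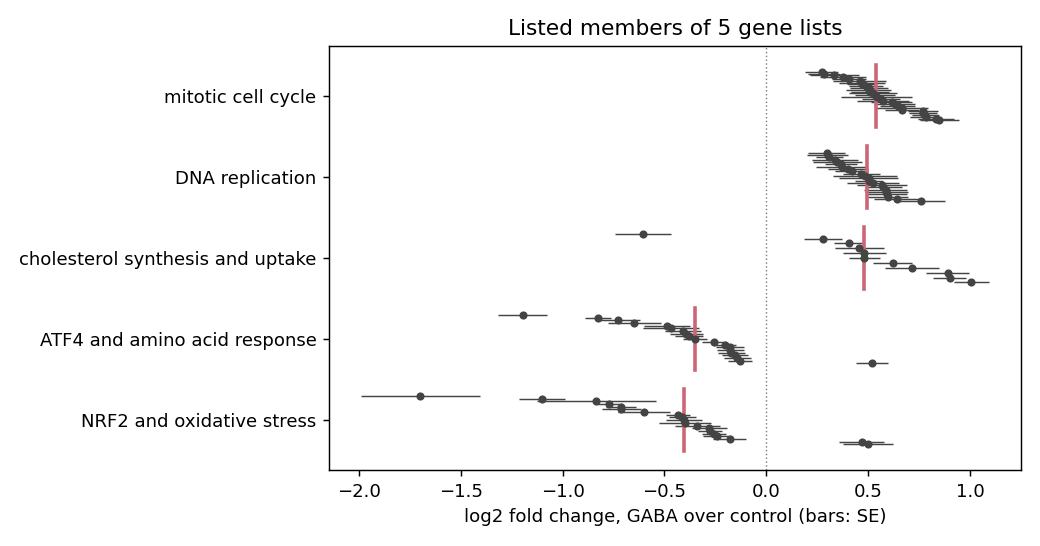
Log2 fold change, GABA over control, of each tested gene in 5 gene lists, with bars for the SE and a red line at the list's median. The mitotic and replication genes all lie above 0, from 0.27 to 0.85, while 17 of 19 genes of the NRF2 and oxidative stress list lie below 0.

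Genes of GABA handling were mostly lower, with 8 of 10 tested genes of synthesis, transport and breakdown down and 2 up, which did not pass the list test (camera adjusted p = 0.30). SLC6A6, the taurine transporter, fell from 64.3 ± 7.15 to 39.0 ± 3.94 CPM (log2 fold change -0.72 ± 0.11, adjusted p = 3.2e-04). SLC6A8, the creatine transporter, had -0.83 ± 0.15, SLC1A5, a glutamine transporter, had -0.33 ± 0.06, and ALDH5A1, which oxidises the product of GABA breakdown, had -0.42 ± 0.10. Of the GABA receptor subunits, 2 were tested, and both fell. GABBR1, a subunit of the metabotropic receptor, had -0.61 ± 0.10 (89.6 to 58.8 CPM, adjusted p = 4.3e-04). GABRG1, an ionotropic subunit, had -1.36 ± 0.39 at 1.84 and 0.705 CPM (adjusted p = 0.0073). GAD1 and ABAT, which make and break down GABA, are not listed in the files used here.

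Genes tied to invasion did not shift one way. Of 11 tested mesenchymal genes 6 rose and 5 fell (camera adjusted p = 0.67), of 8 epithelial genes 5 rose and 3 fell (adjusted p = 0.47), and of 10 genes of matrix proteases and invasion 5 rose and 5 fell (adjusted p = 0.72). Without control replicate 1, 3 mesenchymal genes fell, and without GABA replicate 2, 1 epithelial gene fell. FN1, fibronectin, rose by 0.88 ± 0.06 (1228 to 2257 CPM, adjusted p = 9.6e-07), and LOX, a collagen cross-linking enzyme, by 0.48 ± 0.06. SPARC, a matrix glycoprotein, had -0.76 ± 0.06 (2724 to 1609 CPM, adjusted p = 2.7e-06), and VIM, the intermediate filament vimentin, had -0.26 ± 0.08 (adjusted p = 0.0086). The epithelial junction genes JUP and PKP3 rose by 1.08 ± 0.08 and 0.57 ± 0.09, and KRT19, a keratin, by 0.36 ± 0.06. CLDN1, a tight junction protein, had -0.44 ± 0.08. TIMP3, a protease inhibitor, rose by 0.97 ± 0.07, ADAMTS1, a matrix protease, by 0.92 ± 0.07, and CD44, the hyaluronan receptor, by 0.33 ± 0.06, while ADAM17, a sheddase, had -0.31 ± 0.07. CDH1 is not listed in the files used here.

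Hepatocyte genes were seldom listed. Of 43 hepatocyte secreted proteins, 2 were in the files, and both fell. C3, a complement component, had -0.50 ± 0.14 (22.3 to 15.7 CPM). Both tested hepatocyte transcription factors, FOXA1 (-1.33 ± 0.34) and HNF4G (-0.68 ± 0.18), fell at under 10 CPM. Of 4 tested acute phase genes 3 fell and 1, STAT3, rose, and of 4 bile acid genes 2 rose and 2 fell. AFP and ALB are not listed in the files used here. The markers of immune and endothelial cells, 18 and 13 genes, were not listed at all, and 3 fibroblast markers were tested, of which 2 rose and 1 fell. Of 12 markers of kidney and cervix cell lines 3 were tested and rose: PAX2 from 5.50 to 10.1 CPM, HOXB7 from 111 to 132 and HOXB9 from 232 to 271. Of 13 neuronal markers 3 were tested, with SYP up and MAP2 and SNAP25 down, all below 20 CPM. The identity of the line cannot be checked from the listed genes.

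The largest log2 fold changes belonged to genes with low counts. The 10 largest rises ranged from 2.18 to 3.36 and were AL355032.1, DRGX, NDUFV1-DT, CDC37L1-DT, CYP26B1, ZMYND10, ZBTB8B, AC005481.1, SLC2A2 and SYT11. CYP26B1, which breaks down retinoic acid, went from 1.22 ± 0.75 to 7.54 ± 1.38 CPM (log2 fold change 2.61 ± 0.36, adjusted p = 1.3e-04). SYT11, a synaptotagmin, went from 2.75 ± 0.84 to 12.4 ± 2.06, and SLC2A2, the glucose transporter GLUT2, from 0.334 ± 0.19 to 1.67 ± 0.38. The 10 largest falls ranged from -3.62 to -2.53 and were AL035665.1, ALG1L8P, LINC00243, AC108463.1, C5AR1, ALG1L7P, AL360181.1, KLHL30-AS1, KCNK3 and MIR503. C5AR1, the receptor for complement C5a, went from 3.48 ± 0.38 to 0.537 ± 0.36 CPM (log2 fold change -2.65 ± 0.42, adjusted p = 3.0e-04). ALG1L8P and ALG1L7P are near-copies of other genes, so their reads are uncertain.

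Among genes with a mean of at least 50 CPM, a ranking chosen after the values were seen, the largest rises were those of IL1B and PLAT. IL1B (ENSG00000125538, chromosome 2), the cytokine interleukin-1 beta, rose from 41.7 ± 2.75 to 128 ± 6.61 CPM (log2 fold change 1.61 ± 0.09, adjusted p = 6.7e-07). PLAT (ENSG00000104368, chromosome 8), tissue plasminogen activator, rose from 371 ± 35.4 to 1105 ± 55.7 (1.58 ± 0.08, adjusted p = 2.8e-07). INHBA, the activin subunit, rose by 1.36 ± 0.09, SERPINB2, a plasminogen activator inhibitor, by 1.24 ± 0.11, and STC1, stanniocalcin, by 1.16 ± 0.11. RBM14, ANKRD13A, SLC39A10, JUP and HRNR completed the 10, at 1.02 to 1.32. The 10 falls ranged from -1.34 to -1.10. They were ABCC3, an organic anion exporter, at -1.34 ± 0.12, MKNK2, a kinase of the translation factor eIF4E, at -1.30 ± 0.10, and TXNIP, the thioredoxin-interacting protein, at -1.17 ± 0.08 (931 to 413 CPM, adjusted p = 9.6e-07), with AC006452.1, BEX2, DDIT4, ZP3, ALDH3B1, LINC00963 and OSGIN1.

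**Figure D3:**
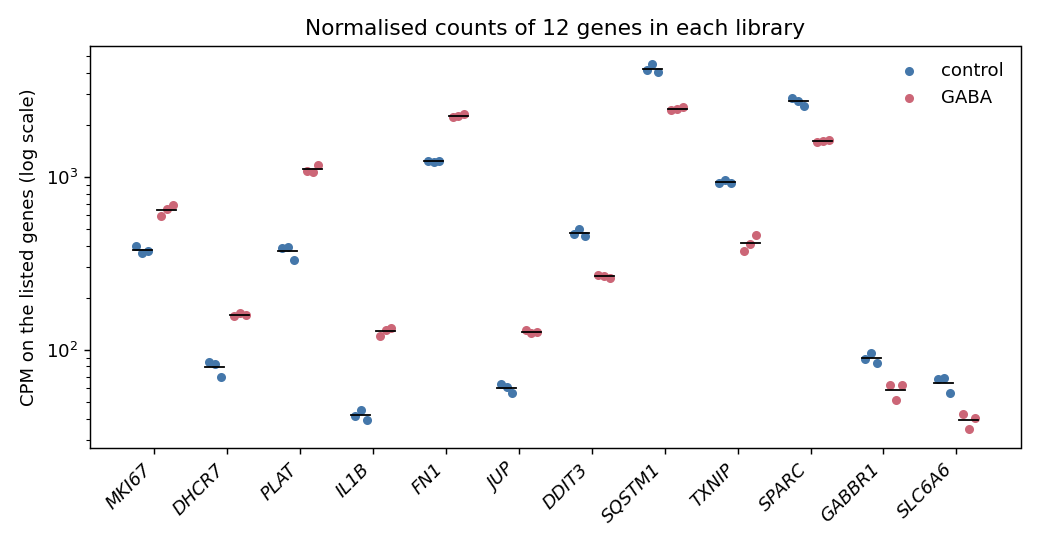
CPM on the listed genes (log scale) of 12 genes in each library, with a point per library, a line at the group mean, control in blue and GABA in red. The 3 GABA libraries lie on the same side of the 3 control libraries for each gene, as for PLAT, from a mean of 371 to 1105.

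The other 35 tested lists did not pass camera. Fisher's exact test of direction against the other listed genes (2-sided, adjusted over the 51 lists) passed the same 5 lists. It also passed the epigenetic regulators (adjusted p = 0.032) and ribosomal proteins (adjusted p = 0.049), but it treats genes as independent. With an estimated correlation, camera gave the epigenetic and ribosomal lists adjusted p = 0.76 each. Of the 16 ribosomal protein genes tested, 11 fell, 1 rose and 4 did not pass (camera adjusted p = 0.10). Of these genes 7 fell with DESeq2 size factors, with DESeq2, and without GABA replicate 1 or 3. With the scaling set to the file order, 15 fell. In each of these settings 1 of the 16 lay above 0. Listed genes named as ribosomal proteins, a wider set, held 4.24% to 4.39% of counts in control and 3.61% to 3.84% in GABA libraries. All 6 cAMP and CREB targets rose (adjusted p = 0.10), among them SGK1, a kinase, by 0.94 ± 0.06 and DUSP1, a phosphatase, by 0.53 ± 0.08. The interferon list had 11 of 13 genes down (adjusted p = 0.11) and the epigenetic regulators 13 of 15 up (adjusted p = 0.12), or 8 up without GABA replicate 2. In the NF-kB list, with 5 up and 6 down, the median was -0.23 while the mean (0.16) and the camera direction lay above 0 (adjusted p = 0.93). The fatty acid oxidation and ketogenesis list, with 2 up and 4 down, also had a median (-0.27) and a mean (0.05) of different sign (adjusted p = 0.72). The NF-kB list held both IL1B and CXCL2, which had -1.27. The 3 tested metallothioneins, metal-binding proteins, fell, at -0.71 for MT1E, -1.16 for MT1X and -0.38 for MT2A.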

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

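The 3 added alternatives were chosen after the data had been seen. In edgeR, DESeq2 and limma-voom, under other scalings and filters and with each library left out, no called gene changed sign. The 78 named genes kept their direction and call in all 1240 gene and setting values. Listed genes differ in this same comparison, and most named genes were picked by p-value or fold change. Both outcomes were therefore largely fixed beforehand. The count of changed genes ran from 4324 with DESeq2 to 5131 without a filter, and from 4025 to 4735 with a library left out. With DESeq2, 54.8% of the called genes were higher, against 48.2%. The replicate block gave 4823 genes. No shared deviation of same-numbered libraries was seen (correlations 0.0003, -0.089 and -0.036). The labels do not say whether a number marks cultures handled together, and these values cannot settle it. A minimum absolute log2 fold change of 1 left 515 genes, 275 higher and 240 lower, by its construction. The same 5 lists passed in each scaling, filter, block and leave-one-out fit. With an estimated correlation 0 lists passed, and the adjusted p was 0.70208 for each of the 5, the mitotic, replication, cholesterol, ATF4 and NRF2 lists. In that order, the unadjusted camera p was 0.122, 0.125, 0.134, 0.062 and 0.025, the last being the 1 list under 0.05. The estimated correlations were 0.31, 0.26, 0.20, 0.05 and -0.02. The NRF2 estimate lay below the preset 0.01, yet its unadjusted camera p was 0.0012 with the preset, against 0.025. A higher correlation therefore does not account for the loss of that list. For the other lists the cause was not tested. The fry test passed 31 lists, since it does not compare a list with other genes. After the length and GC correction 6 lists passed, with the interferon list added (adjusted p = 0.043). Genes without a change are nearly absent from the files, so no alternative can tell how many genes did not respond.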

Other observations

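The gene families described first, and the tests on hepatocyte genes, transcript length, control replicate 3 and other splits, were chosen after the results were seen. The cell cycle genes outside the lists and the decay targets were fixed before their values were seen. Zinc finger genes rose more often than other listed genes, with 66 of 95 up and 29 down and a median log2 fold change of 0.35 (Fisher's exact test, 2-sided; adjusted p = 9.0e-04 over the 33 families looked at by name). It was the 1 family of the 33 that passed, but the test treats genes as independent. Because the families were chosen after the results were seen, its p-value is only descriptive. BMP, SMAD and ID genes, of bone morphogenetic protein signalling, were lower in 11 of 12 (adjusted p = 0.073). Among them ID1 and ID3, inhibitors of differentiation, had -0.79 ± 0.09 and -1.02 ± 0.12 (SE), and SMAD7, an inhibitory SMAD, had -0.54 ± 0.12. HLA-B, HLA-C and B2M, which present peptides to T cells, fell at -0.37, -0.35 and -0.29, while their family as a whole had 3 up and 7 down (adjusted p = 0.64).

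The plasminogen and clotting genes moved both ways. PLAT, F3 (tissue factor, 0.88 ± 0.06), THBS1 (thrombospondin, 0.47 ± 0.06) and SERPINB2 rose, whereas PLAU (urokinase) and TFPI, the tissue factor inhibitor, fell at -0.17 and -0.25. The chemokine CCL5 fell from 69.9 ± 4.07 to 16.3 ± 2.62 CPM (SD, n = 3), and CXCL8, another chemokine, rose from 64.6 to 122. SOX9, a progenitor transcription factor, rose from 417 ± 2.49 to 802 ± 21.9. The list of oncofetal liver cancer markers that holds SOX9 had 2 genes up and 3 down (camera adjusted p = 0.72). TXNIP and its relatives ARRDC3, ARRDC4 and ARRDC1, of the arrestin domain family, had -1.17, -0.84, -0.63 and -0.43, while the family searched by name, with the KLF1x genes, did not pass (adjusted p = 0.15). In all, 29 genes had a count of 0 in the control libraries and 21 in the GABA libraries, with at most 25 and 19 counts in the other group.

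The mitotic, replication and cholesterol lists were higher and the ATF4 and NRF2 lists lower, with adjusted p = 0.70 for each when the correlation was estimated. A trend with transcript length and GC content explained 4.98% of the variance in fold change, and all 5 lists still passed once it was removed, with medians before and after of 0.54 and 0.62 (mitotic), 0.49 and 0.45 (replication), 0.48 and 0.46 (cholesterol), -0.35 and -0.36 (ATF4) and -0.40 and -0.33 (NRF2). With the preset correlation, the calls therefore did not depend on this trend over the listed genes. All 5 also passed without control replicate 3. The listed genes follow the comparison with that library in it, so this fit cannot exclude its part in the calls. Of 26 cell cycle genes outside the lists, 25 rose (96.2%), such as GTSE1 (0.80) and KIF4A (0.65), and CDCA7 fell, while 4 of 6 replication-dependent histone genes fell. The first count was the outcome set beforehand for a larger share of cycling cells in the GABA cultures. A direct effect on these genes or a difference in culture density could give the same count, so it cannot tell them apart. Neither was tested, and both stay open.

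Of 11 host genes of small nucleolar RNAs, 9 fell, 1 rose and 1 did not pass, but the family searched by name, with the microRNA host genes, did not pass (adjusted p = 0.073). The values included SNHG7 at -0.65 ± 0.11 and SNHG8 at -0.61 ± 0.07. Many such transcripts are nonsense-mediated decay targets, and faster decay with GABA was a candidate explanation: of 12 other known targets, 58.3% lay lower, between the shares set beforehand for and against it (over 75% and at most 55%), and 4 of the 12 are themselves host genes, such as GAS5 (-0.45) and ZFAS1 (-0.65). Without host genes, a count made after the values were seen, 3 of 8 lay lower (37.5%, exact 95% interval 8.52% to 75.5%), which goes against it but is too few to exclude it. Of these, UPF1 and SMG5, decay factors whose own transcripts are targets, rose by 0.58 and 0.34.

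Hepatocyte secreted proteins were listed in 4.65% of cases (2 of 43, exact 95% interval 0.568% to 15.8%), against 33.9% for genes that every cell uses (43 of 127; Fisher's exact test, 2-sided, p = 9.2e-05). Scarce hepatocyte transcripts may be a cause, but genes without a change are nearly absent from the files. Of the immune and endothelial markers, 0 of 31 were listed (Fisher's exact test against the hepatocyte proteins, 2-sided, p = 0.51). The 41 hepatocyte members not listed could also have been abundant and unresponsive, so the explanations cannot be told apart here.

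For the genes changed by GABA, the 10 splits of 6 libraries are too few for a share under 0.05; 1 split, the real one with 4918 genes, gave as many, and the highest of the others gave 0. The genes were listed because they differ in the real split, which fixed this outcome beforehand, so it says nothing about chance. For the gene lists, 2 of 10 splits gave 5 lists, the real one and the split of control replicates 1 and 2 with GABA replicate 2 against the rest, which again is too few for a share under 0.05. Lists passed in 8 of the 9 other splits (0 to 5 lists). Each of these has both treatments on both sides in unequal numbers, so part of the treatment difference remains. The splits therefore cannot show how often camera with the preset correlation passes lists without an effect.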
